A study of Homo sapiens with 2 samples.

How the data were processed

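The series holds RNA-seq of Hep3B, an established human hepatocellular carcinoma cell line, as 1 library of untreated cells and 1 library of cells exposed to A4368, a compound given only by this code, at 25 µM for 24 h. Per the labels' protocols, the cells were grown in DMEM with serum and total RNA was isolated on columns. The vehicle, the RNA selection, the strandedness of the libraries and the read depth are not given in the sources used here.

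The authors deposited 1 table with a gene symbol and a value for each library. Its header names no unit. The submitters' processing notes list TopHat2 2.0.12, Bowtie2 2.2.3, Cufflinks and the build hg19, and the values are not whole numbers, so the values deposited by the authors were read as FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library), as Cufflinks estimates them. Of 24302 lines, 11511 held a symbol and both values. The other 12791 lines held no value: 10947 were blank and 1844 held only a locus name. No gene had a mean of the libraries under 0.496 FPKM, so low genes had been removed before deposit, by a rule not given in the sources used here. The annotation was not named either. The table lists CBSL, a copy of CBS that GENCODE release 29 places on another part of GRCh38, and the build behind the table was not settled. No coordinates are therefore given.

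The FPKM values carry no counts. Among 1667 genes with a mean under 3 FPKM, at most 6 shared a library ratio to 3 decimals, so no steps of whole reads were visible and the depth stayed unknown. No interval or detection floor could be given. Cufflinks divides reads of overlapping or near-identical genes by likelihood, which can move the values of such genes in opposite directions.

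The library ratio of each gene was log2((A4368 FPKM + 1)/(control FPKM + 1)), a scale that understates the change of low genes. Folds given in words are plain ratios of the deposited values. Genes with a mean of at least 1 FPKM were kept, which left 11238 and removed 273. With 1 library per group there is no measure of the spread between cultures, so no p-value was computed and every difference is one between these libraries. Size was described by limits of 2-fold and 1.5-fold on the log2 scale with the pseudocount of 1.

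Before the data were examined, 41 gene lists were fixed: liver functions, stress and metabolic pathways, proliferation, signalling targets and markers of other cell types. A list with at least 5 kept members was placed by the percentile of its median ratio among 10000 random lists of the same size, matched on mean FPKM in 20 bins. A list under percentile 2.5 or over 97.5 is said to stand apart. With independent genes, chance would put 1.85 of the 37 lists tested outside these limits. Genes of 1 pathway vary together between any pair of cultures, so the percentiles describe these libraries and are not tests of the compound.

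The genes named in the text followed a rule fixed at the same time, and other genes are named as partners in sequence, as the exceptions in a count or, after their values were seen, for what the sentence says of them. The rule took the 10 highest and 10 lowest ratios among genes with a mean of at least 5 FPKM, up to 4 members with the largest absolute ratio of each list that stood apart, and 1 member of each other list. From a list with under 5 kept members it took up to 2 by mean. This gave 100 genes, of which some are not reported here. Symbols that join the names of neighbouring genes were left out of the rule.

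The alternatives fixed in advance were pseudocounts of 0.1 and 5, no filter and a filter at 5 FPKM, centring on the median ratio of genes with a mean of at least 10 FPKM, and rescaling each library to the same sum without the 50 highest genes. That sum is larger than the deposited one, so the pseudocount of 1 weighs less there. A 1.5-fold limit, list means and unmatched random lists completed them. Chosen after seeing the data were a run without genes that share at least 50% of their sequence with another gene and a correction of the ratios for trends with GC content and length. Both used GENCODE release 29 transcripts, matched by symbol or RefSeq synonym for 99.5% of the kept genes. Shared sequence was the percentage of a gene's distinct 31-base words, on either strand, that occur in transcripts of another gene.

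The procedure was tested on simulated data built from the real means, with independent noise per gene set below the spread between the real libraries. Changed genes were drawn from those with a mean of at least 5 FPKM. The rates that follow check the procedure and are not error rates of these libraries. Of 50 genes changed by 1.5 log2 units upward all were recovered, and of 50 changed downward by that size 94% were recovered, while 0 of 11053 unchanged genes passed the 2-fold limit. Lists of about 20 genes shifted by 0.2 log2 units stood apart in 91% of 100 cases, and unshifted lists in 3%. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.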

Results

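Gene expression was measured by RNA-seq in Hep3B cells, a human hepatocellular carcinoma line, left untreated and in Hep3B cells exposed to 25 µM A4368 for 24 h, with 1 library of each. The comparison asks how the compound alters gene expression across the genome in these liver cancer cells. The table gave FPKM values for 11511 genes, with a median of 13.3 FPKM in the control and 13.5 FPKM in the A4368 library. The depth of the libraries is unknown. There were no replicates, so no value below carries an error from repeated cultures and no difference has a replicate check.

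The profiles differed little for most genes. Of 11238 genes with a mean of at least 1 FPKM, 10879 (96.8%) lay within 1.5-fold of each other on the log2(FPKM + 1) scale. The 2-fold limit was passed by 13 genes that were higher and 49 that were lower with A4368, so that 21.0% of these genes were higher. When both libraries were rescaled to the same larger sum without the 50 highest genes, the split was 31 higher and 66 lower, or 32.0% higher. The ratios had an SD across genes of 0.16 log2 units in the 921 genes at 100 FPKM or more and of 0.34 in the 2476 genes at 1 to 5 FPKM. ALB, which encodes albumin and was picked for its abundance, stood at 9183 FPKM in the control and 8930 FPKM with A4368.

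Among genes with a mean of at least 5 FPKM, the lowest ratios included secreted signalling proteins. NPPB, which encodes the B-type natriuretic peptide, was 3.26-fold lower with A4368, at 41.5 FPKM in the control and 12.7 FPKM after treatment. The chemokine genes CXCL1 and CCL20 were 2.59-fold and 2.32-fold lower. ETV4, an ETS transcription factor gene, was 2.88-fold lower, C8orf4 was 2.46-fold lower and the keratin gene KRT23 was 2.33-fold lower. PIGY, ZNF525, CH507-9B2.3 and CBS were also among the lowest 10, and at least PIGY and CBS cannot be read as single genes. All of the sequence words of PIGY lie in PYURF, which was at 55.8 FPKM in the control and 68.0 FPKM with A4368, while PIGY was listed at 27.6 and 0.00259 FPKM. CBS, which encodes cystathionine beta-synthase, was at 31.6 and 8.44 FPKM and its near-identical copy CBSL at 60.7 and 90.4 FPKM, which sum to 92.4 FPKM in the control and 98.8 FPKM with A4368. ZNF525 shares 19.5% of its words with other genes, and CH507-9B2.3 had no match in the transcript set used.

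The highest ratios were smaller. C4orf48 was at 17.8 FPKM in the control and 44.5 FPKM with A4368, and the sialyltransferase gene ST3GAL3 was 2.45-fold higher at 3.84 and 9.39 FPKM. CYP1A1, the cytochrome P450 gene best known as a target of the aryl hydrocarbon receptor, was 2.03-fold higher. CHAC1, which encodes a glutathione-degrading enzyme, was 1.99-fold higher and DDIT4, an inhibitor of mTORC1 signalling, 1.95-fold higher. The helicase gene DDX41 was 1.95-fold higher, TMEM175, a lysosomal channel gene, 1.99-fold, the zinc finger gene ZNF784 2.09-fold, the diacylglycerol kinase gene DGKQ 1.96-fold and FAM173A 1.84-fold.

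**Figure D1:**
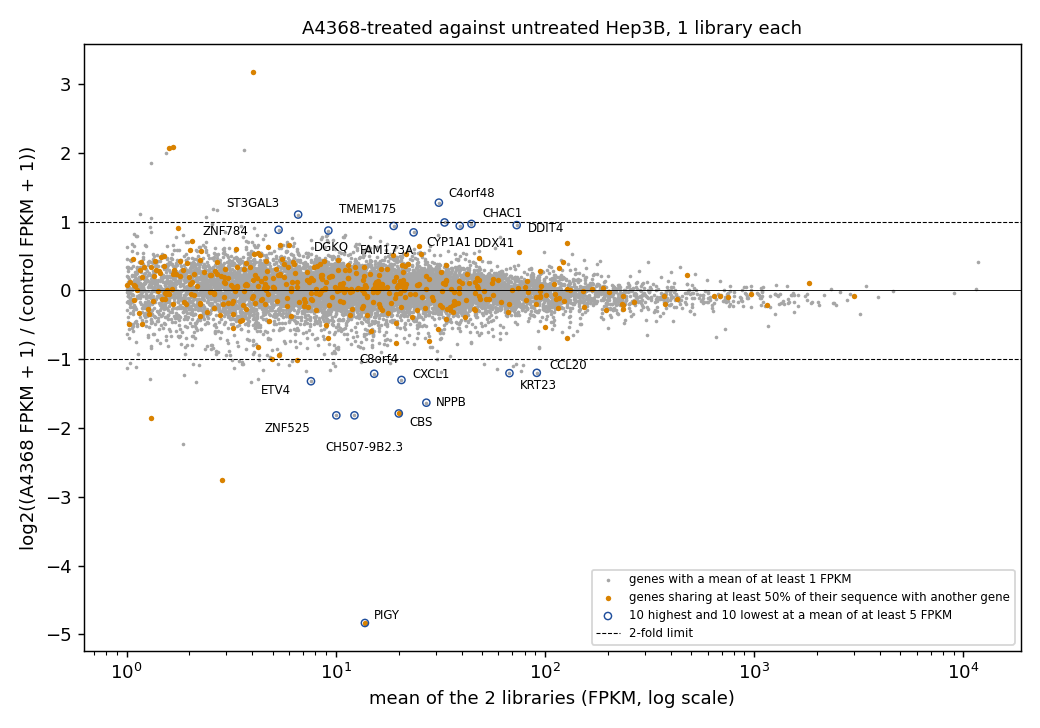
Each point is 1 of 11238 genes; the x axis is the mean of both libraries in FPKM on a log scale and the y axis is the log2 ratio of A4368 to control with a pseudocount of 1 FPKM. Dashed lines mark the 2-fold limit, passed by 13 genes above and 49 below; orange points share at least 50% of their sequence with another gene, and circles mark the 10 highest and 10 lowest genes with a mean of at least 5 FPKM.

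Of the 41 gene lists, 37 had at least 5 measured members, that is, members with a mean of at least 1 FPKM. The median ratios of 9 lists lay below and those of 6 lay above the central 95% of random lists matched on expression, and 22 lay within it.

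Genes under NF-kappaB control and inflammatory cytokines formed the list with the lowest median. All 15 measured members were lower with A4368, with a median log2 ratio of -0.51, below all 10000 random lists, and 6 were lower by at least 1.5-fold. CXCL1, CCL20 and CXCL8, the interleukin-8 gene, passed the 2-fold limit, CXCL8 at 44.8 FPKM in the control and 19.1 FPKM with A4368. CXCL3 was 2.44-fold lower at 4.22 and 1.73 FPKM.

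Targets of the Hippo pathway coactivator YAP were lower as well. All 11 measured members had lower values, with a median log2 ratio of -0.46, again below all 10000 random lists, and 4 were lower by at least 1.5-fold. ANKRD1 was 2.23-fold lower (82.0 FPKM in the control, 36.7 FPKM with A4368), and the matricellular genes CTGF and CYR61 were 1.80-fold and 1.65-fold lower. AMOTL2, which encodes an angiomotin family protein, was 1.60-fold lower.

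Further signalling lists had medians below the random lists. Targets of TGF-beta and genes of epithelial-mesenchymal transition had a median of -0.23 (percentile 0.05), with 11 of 14 members lower. Examples were ID3, an inhibitor of DNA-binding gene, 1.78-fold lower, TGFBI 1.31-fold lower and the intermediate filament gene VIM 1.30-fold lower, and CTGF belongs to this list too. CDH1, CDH2 and ID2 were the members with higher values. WNT and beta-catenin targets had a median of -0.19 (percentile 0.68), with 10 of 12 lower, or 9 after the rescaling. Of these, DKK1, a secreted WNT antagonist, was at 806 FPKM in the control and 506 FPKM with A4368, and the cyclin D1 gene CCND1 was 1.48-fold lower. SP5 and TNFRSF19 were 1.97-fold and 1.60-fold lower from levels under 5 FPKM. The WNT list did not stand apart with a pseudocount of 5 (percentile 2.68) or among genes with a mean of at least 5 FPKM (percentile 13.5). Immediate early genes had a median of -0.16 (percentile 0.79), with 7 of 11 lower. IER3 was 2.13-fold lower, and the phosphatase genes DUSP6 and DUSP1 and the transcription factor gene KLF6 were 1.44-fold, 1.35-fold and 1.42-fold lower. This list was no longer apart once ratios were corrected for GC content and length (percentile 3.81).

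Several liver-related lists were lower. Markers of fetal liver and hepatocellular carcinoma had a median of -0.30 (percentile 0.03), with 7 of 8 members lower. SOX9, a transcription factor of biliary and progenitor cells, was 2.05-fold lower, the keratin gene KRT19 1.35-fold lower, the progenitor marker PROM1 1.30-fold lower and the alpha-fetoprotein gene AFP was at 368 FPKM in the control and 295 FPKM with A4368. IGF2 was the member with a higher value. Of 7 acute phase genes with values, the 6 with a mean of at least 1 FPKM were all lower. Their median was -0.41 (percentile 0.02). ORM2 and ORM1, which encode orosomucoids, were 1.69-fold and 1.37-fold lower. They share 59.3% and 49.8% of their sequence with each other, so their values are not independent. CP, the ceruloplasmin gene, was 1.62-fold lower and C4BPA 1.36-fold lower. Of 8 genes of bile acid synthesis and transport with values, the 6 with a mean of at least 1 FPKM were all lower. Their median was -0.31 (percentile 0.28). SLC27A5, a bile acid ligase gene, was 1.91-fold lower, the bile acid-regulated hormone gene FGF19 1.54-fold lower, BAAT, which conjugates bile acids, 1.39-fold lower and AMACR, which shares 62.1% of its sequence with other genes, 1.14-fold lower. The acute phase and bile acid lists each rest on 6 genes and had too few members to be placed at a filter of 5 FPKM.

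Other hepatocyte lists did not stand apart by their medians. Of 21 plasma protein genes, 17 were lower, or 15 after the rescaling, with a median of -0.09 (percentile 17.9). Their mean of -0.23 did stand apart (percentile 0.18), while their median at a mean of at least 5 FPKM did not (percentile 24.3), the hemopexin gene HPX being 1.77-fold lower. All 8 measured genes of the urea cycle and amino acid catabolism had lower values as deposited and 4 of them after the rescaling, with a deposited-scale median of -0.13 (percentile 6.23), and the mean of -0.25 stood apart (percentile 0.94). At a mean of at least 5 FPKM the median of this urea cycle list was at percentile 41.8. HPD, an enzyme of tyrosine breakdown, was 1.85-fold lower. Drug-metabolising enzymes and transporters had a median of -0.12 (percentile 5.13), with UGT2B15 1.81-fold lower. Liver transcription factors had a median of 0.04 (percentile 83.1), with the bile acid receptor gene NR1H4 1.56-fold lower. Gluconeogenesis genes had a median of 0.19 (percentile 94.6), with PCK2 1.48-fold higher.

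MYC targets and ribosome biogenesis genes were lower by small amounts. Of 23 members, 22 were lower, all but BOP1 and none by 1.5-fold, with a median of -0.17 (percentile 0.06). After the rescaling 20 were lower. NOP16, PPAN, NIP7 and NOLC1, which act in ribosome assembly, were 1.38-fold, 1.33-fold, 1.32-fold and 1.27-fold lower, and PPAN shares 56.6% of its sequence with other genes. The cytosolic ribosomal proteins themselves had a median of -0.07 (percentile 60.9), with RPL11 1.17-fold lower.

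Targets of ATF4 and the integrated stress response were higher. Of 29 measured members 24 were higher, or 25 after the rescaling, with a median log2 ratio of 0.18, above all 10000 random lists, and 3 were higher by at least 1.5-fold. These were CHAC1, DDIT4 and the asparagine synthetase gene ASNS, which was 1.54-fold higher at 45.7 FPKM in the control and 70.3 FPKM with A4368. PPP1R15A, which encodes a phosphatase subunit acting on eIF2 alpha, was 1.39-fold lower. Chaperones of the endoplasmic reticulum and genes of the unfolded protein response had a median of 0.01 (percentile 93.2), with 10 of 20 higher, or 14 after the rescaling, and none different by 1.5-fold. The largest ratio there was that of DNAJB9, 1.16-fold higher. Cytosolic heat shock genes had a median of -0.10 (percentile 11.5), with HSPB1 1.19-fold lower.

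Targets of the oxidative stress factor NRF2 were higher, with 14 of 19 members higher, or 17 after the rescaling, and a median of 0.13 (percentile 99.8). SRXN1, which encodes sulfiredoxin, was 1.60-fold higher, although 84.9% of its sequence is shared with another annotated gene. OSGIN1 was 1.48-fold higher and the ferritin light chain gene FTL 1.34-fold higher, FTL being at 10063 FPKM in the control and 13447 FPKM with A4368. The NRF2 targets HMOX1 (42.2 FPKM in the control, 37.2 FPKM with A4368) and NQO1 (73.7 and 63.0 FPKM), picked after their values were seen, were lower. Of 8 aryl hydrocarbon receptor targets 5 were higher, and the members that differed by at least 1.5-fold were CYP1A1, which was higher, and UGT1A6, which was lower at 11.5 FPKM in the control and 6.77 FPKM with A4368. UGT1A6 shares 61.8% of its sequence with other genes. The list had a median of 0.14 (percentile 96.2). Metallothioneins and the zinc exporter gene SLC30A1 had a median of 0.12 (percentile 78.7), with SLC30A1 1.35-fold higher.

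Lipid pathways were among the higher lists. Cholesterol synthesis genes and SREBP2 targets had a median of 0.18, above all 10000 random lists, with 19 of 25 members higher and none by 1.5-fold. MVK, IDI1 and TM7SF2, enzymes of sterol synthesis, were 1.41-fold, 1.34-fold and 1.29-fold higher. Fatty acid oxidation genes and PPAR alpha targets had a median of 0.23, also above all 10000 random lists, with 11 of 15 higher, or 12 after the rescaling. CREB3L3, a liver transcription factor gene, was 2.03-fold higher at 1.90 and 3.86 FPKM, CPT1A, which controls entry of fatty acids into mitochondria, 1.45-fold, ACAA1 1.31-fold and HADHA 1.28-fold. Fatty acid and triglyceride synthesis genes had a median of 0.06 (percentile 87.1), with MLXIPL 1.43-fold higher.

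Autophagy and lysosome genes had a median of 0.09 (percentile 98.7), with 13 of 22 higher, or 17 after the rescaling. The kinase gene ULK1 was 1.53-fold higher, and the autophagy receptor gene SQSTM1 and GABARAPL1 were each 1.33-fold higher, whereas WIPI1 was 1.28-fold lower. Nuclear-encoded oxidative phosphorylation genes were placed at percentile 98.3 although 15 of 30 were higher and their median was within 0.01 log2 units of 0 as deposited, since matched random lists lay between -0.12 and -0.0048. After the rescaling 22 of the 30 were higher, with a median of 0.05. NDUFV1 and UQCRC1 were 1.16-fold and 1.13-fold higher and NDUFV2 was 1.27-fold lower. Neither list was apart from random lists that were not matched on expression (percentiles 93.8 and 41.0), and the autophagy list was not apart after correction for GC content and length (percentile 92.9).

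**Figure D2:**
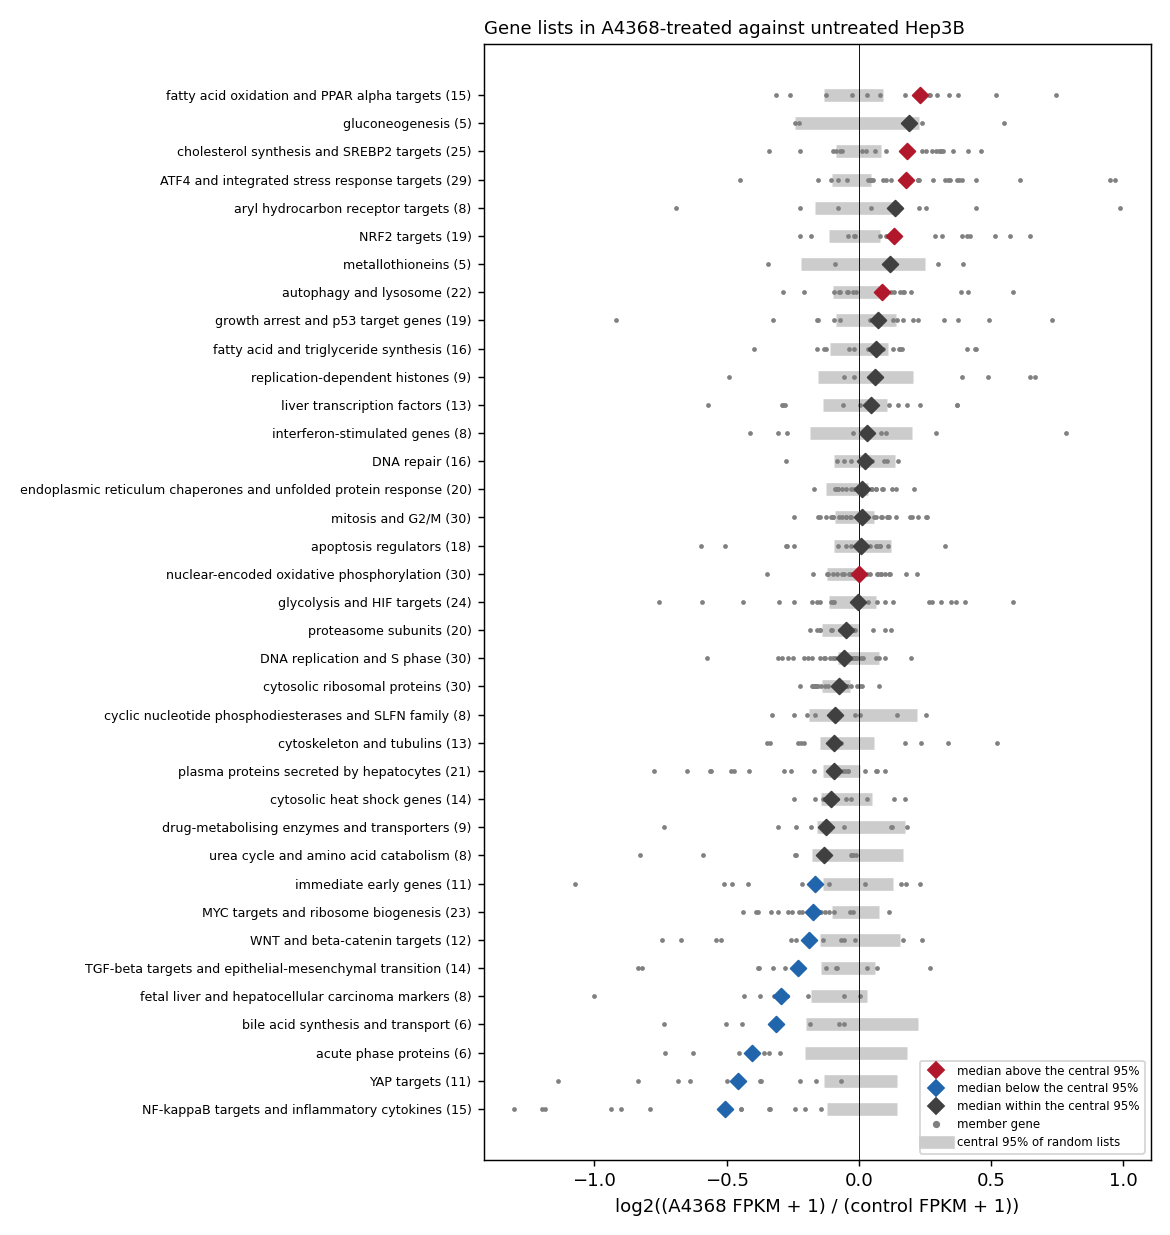
Each row is 1 of the 37 gene lists with its number of measured members in parentheses; the x axis is the log2 ratio of A4368 to control with a pseudocount of 1 FPKM, small points are member genes, diamonds are list medians and grey bars the central 95% of 10000 random lists matched on expression. The lowest medians are those of NF-kappaB targets (-0.51) and YAP targets (-0.46), and the highest is that of fatty acid oxidation genes (0.23).

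Proliferation and cell death lists did not stand apart. DNA replication and S phase genes had a median of -0.06 (percentile 8.95), with 24 of 30 lower, or 15 after the rescaling, and POLE2 1.54-fold lower. Mitosis genes had a median of 0.01 (percentile 80.9), with TTK 1.20-fold higher, and DNA repair genes a median of 0.02 (percentile 44.1), with PALB2 1.23-fold lower. Growth arrest genes and p53 targets had a median of 0.07 (percentile 77.9), with the kinase gene PLK2 2.47-fold lower at 3.80 and 1.54 FPKM. Apoptosis regulators had a median of 0.01 (percentile 44.6), with the survival gene BCL2L1 1.52-fold lower, at 172 FPKM in the control and 113 FPKM with A4368. Replication-dependent histones had a median of 0.06 (percentile 63.1), with HIST2H2BE 2.13-fold higher from 1.07 FPKM.

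The remaining lists also lay within the random range. Glycolysis and HIF targets had a median within 0.01 log2 units of 0 (percentile 66.5), or 0.05 after the rescaling, with EGLN3 2.89-fold lower from 1.66 FPKM. Interferon-stimulated genes had a median of 0.03 (percentile 53.7), with IRF7 2.02-fold higher at 2.39 and 4.83 FPKM. Proteasome subunits had a median of -0.05 (percentile 72.3), which was above 0 after the rescaling, with PSMC4 1.14-fold lower. Cytoskeletal genes and tubulins had a median of -0.09 (percentile 16.4), with TUBB3 1.46-fold higher. Cyclic nucleotide phosphodiesterases and SLFN family genes had a median of -0.09 (percentile 12.5), with PDE3A 1.46-fold lower at 1.78 and 1.22 FPKM.

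Markers of other cell types were few in this cell line. No endothelial marker of the 10 chosen had a value, and 2 of 10 stellate cell and fibroblast markers did, LUM at 17.9 FPKM in the control and 11.9 FPKM with A4368 and RGS5 at 0.98 and 1.64 FPKM. Of 14 leukocyte markers 3 had values, namely CD68, the lysozyme gene LYZ and CD14, which lay outside the rule for named genes. CD68 was 1.07-fold lower and LYZ was at 17.6 and 9.48 FPKM. CD68 shares 81.3% of its sequence with other genes. None of the 13 mitochondrially encoded messengers was analysed here.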

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

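The run without genes that share most of their sequence and the correction for GC content and length were chosen only after the result was seen. The counts of genes past the 2-fold limit depended on how low values were treated. With a pseudocount of 0.1 they were 38 higher and 102 lower, with a pseudocount of 5 they were 2 and 15, and at a mean of at least 5 FPKM they were 2 and 28. Rescaling to a common sum without the 50 highest genes gave 31 higher genes and moved the median ratio by 0.05 log2 units, and a 1.5-fold limit gave 121 higher and 238 lower. Lower genes outnumbered higher ones under each of these settings. The number of lists standing apart stayed between 12 and 17 under all alternatives, against 15 as reported, and no list moved from one side to the other. The aryl hydrocarbon receptor list came to stand apart with a pseudocount of 0.1 (percentile 99.3), after rescaling (percentile 98.3) and without genes sharing at least 50% of their sequence (percentile 99.6), as did the histones in the last case (percentile 98.4). The aryl hydrocarbon receptor list lay further inside the random range with a pseudocount of 5 (percentile 87.4) and at a mean of at least 5 FPKM (percentile 47.2). Acute phase genes could not be placed without genes sharing most of their sequence, having under 5 members left. The lists that lost their place did so under settings given with their values in the results, and the cause was not tested. Of the named genes, SOX9 sat at the 2-fold limit and lay short of it under 4 alternatives, ETV4, C8orf4 and ST3GAL3 lay short of it with a pseudocount of 5, and none of those past the limit changed direction under any alternative that kept it. The single library per condition and the unknown depth limit the comparison. No paired analysis was possible because each condition has 1 library.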

Other observations

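The tests of genes sharing at least 50% of their sequence and of genes held by several lists were chosen, in the form given, only after the result was seen, and the criterion of the former on partners replaced one on the sum of each pair, which the size of the partners made uninformative. The other tests were also devised after the extreme genes and lists had been seen, with their bounds set before their own values were computed, although the shared sequence of some extreme genes had been looked at before the bound for genes sharing under 10% was set.

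All 9 measured genes of the CXCL chemokine family were lower with A4368, 6 of them by at least 1.5-fold. CXCL1, CXCL2, CXCL3 and CXCL8 also belong to the fixed NF-kappaB list, and the family was chosen after its values were seen. The 9 genes included CXCL5 (2.14-fold lower), CXCL6 (8.64 FPKM in the control, 3.74 FPKM with A4368) and CXCL2 (3.51 and 1.61 FPKM), and the log2 ratio closest to 0 was that of CXCL16 (-0.16, at 40.3 and 35.9 FPKM). The endothelin gene EDN1, the bone morphogenetic protein gene BMP2, the thrombospondin gene THBS1 and PTHLH, which encodes parathyroid hormone-related protein, were 2.44-fold, 2.18-fold, 2.14-fold and 2.05-fold lower. GJA1, the connexin 43 gene, and RGS2, a regulator of G protein signalling, were 2.17-fold and 2.27-fold lower. These 6 genes were picked singly after their values were seen and stand for no group.

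The lower values of ETV4, SPRY1, DUSP6, CCND1 and IER3 prompted the hypothesis of lower expression of ERK pathway output genes as a group, tested on 16 other such genes, of which 12 were measured. Their median log2 ratio of -0.45 lay at percentile 0 of 10000 matched random lists, whose central 95% ran from -0.13 to 0.17, and 10 of 12 were lower. DUSP4 was at 4.59 FPKM in the control and 1.78 FPKM with A4368, SPRY4 at 2.87 and 1.40 FPKM, EPHA2 at 27.9 and 16.2 FPKM and PHLDA1 at 34.5 and 21.3 FPKM, whereas EGR1, which with MYC also belongs to the immediate early list, was at 7.56 and 8.55 FPKM. The values are consistent with lower ERK pathway output in the A4368 library, which remains a hypothesis found and tested on the same libraries. The compound and differences between cultures, such as density or vehicle, may each act on these genes, and 1 library per condition does not separate them.

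The genes past the 2-fold limit divide by how much sequence they share with others. Of 56 with a sequence, 8 shared at least 50% of it, above the central 95% of expression-matched random sets (0 to 6). In 5 of 6 pairs with a listed partner the partner moved the other way, as in CBS and CBSL or SMIM11A (0.016 and 3.30 FPKM) and SMIM11B (22.7 and 16.1 FPKM). So few pairs could give this count by direction alone. The values are such as reads divided differently between names that share sequence could give. Not all of these pairs are copies of a gene, since CHURC1-FNTB and TGIF2-C20orf24 join the names of neighbouring genes. Another 37 of the 56 shared under 10% of their sequence. The test for those counted the property by which they were picked, and no such share over all genes was set beside it. It therefore cannot decide on shared reads for them. An effect of the compound on them stays open and untested.

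Genes higher by at least 1.5-fold had GC-rich transcripts, with a median of 58.5% against 47.8% for all genes. Genes lower by 1.5-fold had a median of 50.6%. Among random sets of genes, the medians of the higher and lower genes lay at percentiles 100 and 99.7, so both were on the GC-rich side. The values argue against a difference between the libraries that rises or falls steadily with GC content. Of 5 equal groups by GC content, the highest and lowest differed in median ratio by 0.00265 log2 units. Among genes above and below the median expression they differed by 0.02 and -0.01. Their medians of 0.039 and 0.037 both lay above that of all kept genes (0.0098), so a dependence that raises both ends was not excluded. A wider spread of ratios in GC-rich genes stays open. It was examined only in the 6798 genes with a mean of at least 10 FPKM. There, the interquartile range in the highest GC group was 1.20 times that of the middle group. This value lay between the bounds set for and against a wider spread. The highest of the 5 groups held 59 of the 115 genes higher and 49 of the 234 genes lower by 1.5-fold. The excess in that group was therefore mainly on the higher side. An effect of the compound on these genes was not tested.

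The 9 lower lists were set against technical explanations. After correction of the ratios for GC content and length 8 of the 9 still stood apart, which argues against such a trend for those, the immediate early genes being the exception. CTGF or MYC, the genes found in more than 1 of the lists, belong to the YAP, TGF-beta, MYC and immediate early lists. Without them, 4 of these 4 still stood apart. Each list lost only 1 member, and MYC (log2 ratio -0.11) lay above the medians of its lists (-0.17 and -0.16). Leaving MYC out could not raise those medians, so the check cannot decide on shared genes as the reason. Differences between cultures unrelated to the compound stay open, and so does an effect of A4368.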
